A study of Mus musculus with 12 samples.

How the data were processed

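The study measured total RNA from the paw joints of 12 mice in 3 groups of 4, each library made from 1 animal per the labels. Naive mice received anti-gp120, a control antibody. The remaining mice received arthritogenic serum of K/BxN mice, which carries antibodies that cause joint inflammation, and were given either anti-gp120 or the agonistic anti-SIRPa antibody 6F2. SIRPa is an inhibitory receptor of myeloid cells that binds CD47. The joints of the serum-transferred mice were taken at day 7. Libraries came from a stranded total RNA kit per the labels' protocols. The replicate numbers only name animals.

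The deposited files hold whole-number counts of reads per gene, with no normalization by the authors, and the submitters' processing notes name genome build GRCm38. The aligner, the counting program, its strand setting and its handling of reads that match several genes are not given in the sources used here. For this reason antisense, overlapping and near-identical genes, such as globins, histones, Saa genes, ribosomal protein genes and immunoglobulin segments, are uncertain. Each file lists 52636 gene identifiers, of which 52403 were found in GENCODE M21 on the same build, and identifiers without a symbol held 0.024% of all counts. In total 15225 identifiers had no count in any library. All 12 sample files held the same values as the table of the whole series. Total counts ran from 6893969 to 17597920 per library, so that 3 counts, taken as the detection floor of a gene at 0, correspond to between 0.17 and 0.394 CPM. Intervals on counts and this floor cover counting error only, since no molecular identifiers were used. No pair of libraries within a group agreed within sampling noise: the lowest chi-square per gene was 8.95, between anti-SIRPa 1 and 2.

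Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 16674 genes, libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion was fitted to all 12 libraries with 1 coefficient per group. The biological coefficient of variation was 0.334. The 3 comparisons were control-antibody arthritis against naive, anti-SIRPa against control-antibody arthritis, and anti-SIRPa against naive. Adjusted p values of genes come from the edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment over the tested genes, with a threshold of 0.05. CPM values are TMM-scaled CPM computed from the deposited counts, given as mean ± SD of 4 mice, and fold changes are log2 values with their SE.

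In all, 38 gene lists were fixed before the data were examined, covering immune and joint cell types, other tissues of the paw, signalling programs and library properties. Of these, 37 had at least 5 measured members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison; camera with an estimated correlation and fry were run beside it. The sex-linked list had 1 measured member and was not tested. Where a list was compared per mouse, the mean log2 CPM of its members was tested with an exact two-sided permutation test, for which 0.0286 is the smallest p that 4 against 4 can give. The genes named in the text were chosen by a rule also fixed before the data were examined: per comparison the 10 highest and 10 lowest fold changes among genes past the threshold whose groups did not overlap, with mean log2 CPM of at least 1, leaving out numbered gene models and antigen receptor segments; up to 4 members with the smallest p of each list; and Sirpa, Cd47, Ptpn6 and Ptpn11. Where no gene passed, the rule took the 5 smallest p values in each direction. Not every gene that the rule took is reported here. Any gene named outside the rule is marked as chosen after its values were seen.

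The tests were tried on simulated counts in which the cell cycle list was lowered 2-fold, and its calls were not counted as false. In the same counts 200 genes with a mean of at least 1 CPM had been changed, so that the rates do not cover genes below this level. At 2-, 4- and 8-fold, edgeR recovered 44.8%, 80.6% and 95.5% of the 200 for arthritis against naive among 16281 genes, 47.8%, 76.1% and 93.9% for anti-SIRPa against control antibody among 16265 genes, and 49.3%, 86.6% and 97.0% for anti-SIRPa against naive among 16218 genes. Of its calls, 2 of 152, 8 of 155 and 9 of 164 were false. DESeq2 1.42.0 made 33, 30 and 40 false calls on the same counts. The simulated genes varied independently of each other, without differences between libraries in skin or background reads. These rates therefore need not hold for the real counts.

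The alternatives tried were other size factors, scaling without abundant gene lists, no filter, a filter of at least 1 CPM in 4 libraries, DESeq2, limma-voom, a fit without robust dispersion, a fit of only the 2 groups compared, the replicate number as a block, muscle and erythroid list means as covariates, a 2-fold minimum, and leaving out each mouse. After the data were seen, 5 were added: the newer quasi-likelihood fit, the epidermal list mean as a covariate, leaving out the 2 libraries poorest in skin transcripts, leaving out the 2 libraries with background reads, and subtracting a background in proportion to gene length. Because the same control-antibody libraries enter the arthritis and the treatment comparison, the relation of their fold changes was also computed on 20 simulated data sets of unchanged groups and with the control libraries split 2 and 2. Figures were drawn with matplotlib.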

Results

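RNA was counted in paw joints of 12 mice, 4 naive mice given a control antibody, 4 mice with serum-induced arthritis given the same antibody, and 4 arthritic mice given anti-SIRPa. Total counts were 14289363 to 16205593 in the naive libraries and 13791454 to 17597920 in the anti-SIRPa libraries. In the control-antibody arthritis libraries they were 6893969 to 13416033, with control 2 lowest. The first principal component held 38.3% of the variance and followed epidermal keratins: the epidermal list took 0.00455% of counts in naive 4 and 0.00508% in anti-SIRPa 2, against 1.86% in naive 1 and 2.77% in anti-SIRPa 4. The second held 25.8% and followed Cxcl5, Saa3 and Il1b. On it, controls 2, 3 and 4 lay at -85.8, -72.4 and -41.2, and control 1 at 27.2, among the naive libraries.

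The first comparison asks what arthritis changed in joints of mice without the agonist. The genes with the largest increases included chemokines, interleukin 1 beta and a matrix-degrading enzyme. Cxcl5, which attracts neutrophils, rose by 7.85 ± 1.04 (log2, SE) from 0.101 ± 0.0887 to 25.9 ± 19.1 CPM (SD, n = 4 per group; edgeR adjusted p = 0.00535). Mmp3, which cleaves cartilage matrix, rose by 5.44 ± 0.79 from 2.23 ± 0.294 to 97.4 ± 74.2 CPM (edgeR adjusted p = 0.00807). Il1b, a central inflammatory cytokine, had 1 count in all naive libraries and 422 in the arthritic ones, a ratio of 522 with a counting interval of 93.3 to 20700 (edgeR adjusted p = 0.00763). Saa3, an acute phase protein whose reads can be shared with other Saa genes, was at 0 in all naive libraries and at least 50.9-fold higher in arthritis against a floor of 3 counts per library (edgeR adjusted p = 0.0178). In the other direction Csrp3, a sarcomere protein of muscle, fell from 740 ± 213 to 77.6 ± 48.6 CPM, a change of -3.25 ± 0.45 (edgeR adjusted p = 0.00535). On GRCm38, Cxcl5 (ENSMUSG00000029371) lies on chromosome 5 from 90759360 to 90761624 and Mmp3 (ENSMUSG00000043613) on chromosome 9 from 7445822 to 7455975. Il1b (ENSMUSG00000027398) lies on chromosome 2 from 129364570 to 129371139 and Csrp3 (ENSMUSG00000030470) on chromosome 7 from 48830398 to 48848033, and all are protein-coding.

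**Figure D1:**
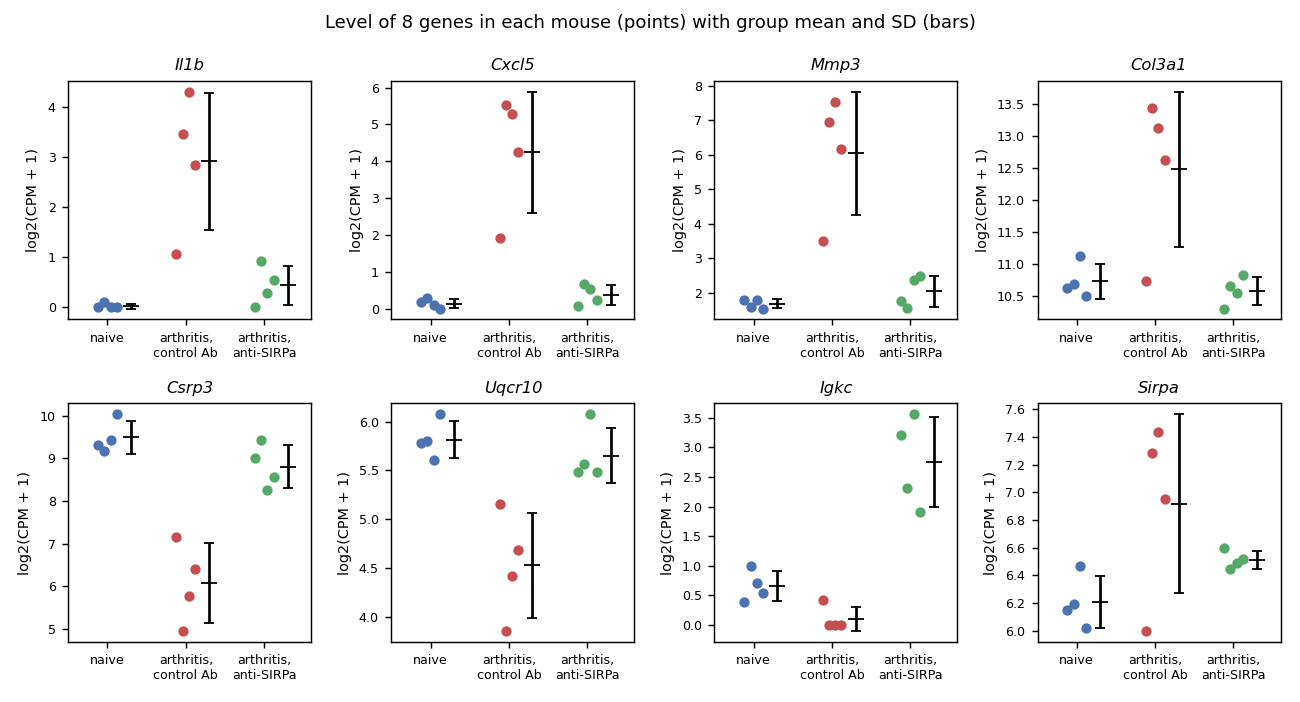
Level of 8 genes in each mouse as log2(CPM + 1), by group; each point is 1 mouse and the bar beside the points is the group mean with its SD. Il1b, Cxcl5, Mmp3 and Col3a1 are high in controls 2, 3 and 4, and control 1 lies nearest the naive mice among the 4 control-antibody mice for these genes.

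Among the other large increases, the monocyte attractant Ccl7 rose by 5.09 ± 0.67, the neutrophil attractant Cxcl1 by 5.01 ± 0.75, the protease inhibitor Slpi by 4.83 ± 0.90, Tnfsf11, the cytokine that drives osteoclast formation, by 4.78 ± 0.85, haptoglobin (Hp) by 4.58 ± 0.94 and the hyaluronan-binding Tnfaip6 by 4.39 ± 0.82. Of these, Tnfaip6 was no longer called without naive 4 (edgeR adjusted p = 0.0526), nor Hp without naive 1, 2, 3 or 4 (edgeR adjusted p = 0.0584, 0.0627, 0.0511 and 0.0669). Beside Csrp3, the genes with the largest decreases by the naming rule were Hectd2os (-2.64 ± 0.53), Gbp10 (-2.52 ± 0.54), the slow muscle light chain Myl2 (-2.48 ± 0.27), the muscle deaminase Apobec2 (-2.37 ± 0.39), Igsf1 (-2.32 ± 0.40), Hottip (-2.26 ± 0.48), Fgf6 (-2.17 ± 0.29), the cartilage lectin Clec3a (-2.14 ± 0.34) and Nmrk2 (-2.13 ± 0.43). The call of Gbp10 was lost without control 2 or control 4 (edgeR adjusted p = 0.0519 and 0.0512) and that of Hottip without naive 4 (edgeR adjusted p = 0.0507). Hectd2os is annotated as antisense, so its reads cannot be told from those of its partner if the counting ignored strand.

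The list of inflammatory cytokines and chemokines had 11 of 20 measured members higher and 0 lower. There were 14 and 0 adjusted over the list alone, with a median of 1.95 (camera adjusted p = 9.27e-08, adjusted p = 0.455 with an estimated correlation). Ccl2 rose by 3.10 ± 0.48. Of 20 matrix-degrading enzymes and inhibitors, 10 rose and 1 fell. There were 14 and 1 adjusted over the list alone, with a median of 1.39 (camera adjusted p = 1.79e-05, adjusted p = 0.455 with an estimated correlation). Timp1, an inhibitor of metalloproteinases, rose by 4.37 ± 0.66, and the aggrecanase Adamts4 by 3.79 ± 0.70. The matrix and tissue repair list had 12 of 22 members higher and 0 lower. There were 15 and 0 adjusted over the list alone, with a median of 1.24 (camera adjusted p = 3.21e-05, adjusted p = 0.455 with an estimated correlation). Cthrc1, a secreted protein of activated fibroblasts, rose by 3.85 ± 0.63 and the collagen Col5a2 by 1.84 ± 0.37. In the libraries of this group, the lincRNA Gm26917 took 5.64 ± 2.39% of counts, against 1.95 ± 0.324% in naive libraries, and the muscle list 8.88 ± 2.92% against 12.2 ± 0.968%. Genes of smell and taste receptors together reached 545 and 215 CPM in controls 2 and 4, 29.3 in control 3 and 7.89 in control 1, against 8.11 to 11.5 in naive libraries.

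Myeloid markers were higher as well. Of 21 monocyte and macrophage genes, 12 rose and 1, Lyve1, fell (16 and 1 adjusted over the list alone; median 0.88, camera adjusted p = 1.25e-06, adjusted p = 0.455 with an estimated correlation). Fcgr1, a high-affinity Fc receptor, rose by 2.38 ± 0.44, Ms4a7 by 2.1 ± 0.41 and Mpeg1, a pore-forming macrophage protein, by 1.96 ± 0.34. Of 22 Fc receptor and complement genes, 9 rose and 0 fell. There were 16 and 1 adjusted over the list alone, with a median of 0.89 (camera adjusted p = 8.2e-06, adjusted p = 0.455 with an estimated correlation). C3 rose by 1.34 ± 0.26 and Cfb by 2.16 ± 0.41, both of the complement pathway. The mature neutrophil list had 4 of 10 members higher and 0 lower. There were 6 and 0 adjusted over the list alone, with a median of 2.09 (camera adjusted p = 0.000169, adjusted p = 0.455 with an estimated correlation). The chemokine receptor Cxcr2 rose by 4.49 ± 0.84 and the lectin receptor Clec4d by 3.87 ± 0.58. The dendritic cell list had 4 of 13 higher and 0 lower. There were 9 and 0 adjusted over the list alone, with a median of 1.39 (camera adjusted p = 0.000468, adjusted p = 0.455 with an estimated correlation). The 4 called members, Ciita, Batf3, Fscn1 and H2-Eb1, were all lost without naive 1, 2 or 4 or control 2 or 3 (edgeR adjusted p from 0.0528 to 0.148). The interferon response list had 8 of 20 higher and 0 lower. There were 14 and 0 adjusted over the list alone, with a median of 1.31 (camera adjusted p = 5.88e-06, adjusted p = 0.455 with an estimated correlation). Among interferon-induced genes, Zbp1 rose by 2.35 ± 0.47 and Oasl2 by 1.88 ± 0.38. The list of the SIRP family and phosphatases also holds other receptors and adaptors of myeloid cells. Of its 14 measured genes, 7 rose and 0 fell, among them the inhibitory receptors Clec12a (1.60 ± 0.28) and Pirb (1.34 ± 0.24), which are not SIRP genes. There were 9 and 1 adjusted over the list alone, with a median of 0.87 (camera adjusted p = 7.47e-05, adjusted p = 0.455 with an estimated correlation).

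The immediate early list, genes switched on within minutes of a stimulus, had 7 of 16 members higher and 0 lower. There were 9 and 0 adjusted over the list alone, with a median of 0.75 (camera adjusted p = 8.01e-05, adjusted p = 0.455 with an estimated correlation). Zfp36, which destabilises cytokine messenger RNA, rose by 1.31 ± 0.19 and Junb by 1.35 ± 0.23. The cell cycle list had 2 of 24 members higher, Mcm2 and Mcm3, and 0 lower. There were 10 and 0 adjusted over the list alone, with a median of 1.58 (camera adjusted p = 8.62e-07, adjusted p = 0.455 with an estimated correlation). The osteoclast list had 2 of 13 higher, Tnfsf11 and the proton pump subunit Tcirg1, and 0 lower. There were 6 and 1 adjusted over the list alone, with a median of 1.00 (camera adjusted p = 0.0109, 0.0734 without control 2, adjusted p = 0.459 with an estimated correlation). Tnfsf11 is made by stromal and immune cells and acts on osteoclast precursors. Without control 2 the osteoclast median was 0.61.

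Genes of energy metabolism and muscle were lower. In controls 1, 2, 3 and 4 the mean log2 CPM of the respiratory chain list was 5.558, 4.675, 4.892 and 5.12. That of the muscle list was 11.817, 10.419, 10.659 and 11.191, with the mice in the same order. These values do not tell a change of energy metabolism from a smaller share of muscle RNA. Of 78 nuclear-encoded respiratory chain genes, 30 fell and 1 rose. There were 53 and 1 adjusted over the list alone, with a median of -0.57 (camera adjusted p = 1.08e-17, adjusted p = 0.455 with an estimated correlation). Uqcr10 changed by -1.25 ± 0.24, from 55.7 ± 7.77 to 23.3 ± 8.81 CPM, and Ndufb5 by -0.90 ± 0.16. The member that rose was Cox7c (1.32), named here after its value was seen. Of 22 skeletal muscle genes, 4 fell and 0 rose: Eno3 (-1.50 ± 0.36), Myl1 (-1.50 ± 0.42), Myh2 (-0.95 ± 0.27) and Myh7 (-0.81 ± 0.24). There were 8 and 0 adjusted over the list alone, with a median of -0.57 (camera adjusted p = 1.25e-06, adjusted p = 0.455 with an estimated correlation). The glycolysis and hypoxia list had 2 of 17 members lower, the lactate transporter Slc16a3 (-1.03 ± 0.21) and Ldha (-0.43 ± 0.12), and 1 higher, Hif1a (1.03 ± 0.28). There were 4 and 1 adjusted over the list alone, with a median of -0.33 (camera adjusted p = 0.00709, adjusted p = 0.394 with an estimated correlation). The Schwann cell and nerve list had 2 of 14 members lower, Pou3f1 (-1.20 ± 0.23) and Gldn (-1.05 ± 0.22; edgeR adjusted p = 0.0505 without control 3), and 0 higher (median -0.38, camera adjusted p = 0.000169, adjusted p = 0.455 with an estimated correlation). Without control 1 the skeletal muscle median was -0.96.

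In all, edgeR called 1721 of 16674 genes, 979 higher and 742 lower, of which 800, 575 higher and 225 lower, changed at least 2-fold. With limma-voom the balance was the opposite, 486 higher and 677 lower. Among the called genes, 1152 had groups that did not overlap, and among all tested genes 12.49% did, against 2.86% by chance. The count was 720, 619, 888 and 469 without naive 1, 2, 3 and 4, and 4694, 611, 412 and 664 without control 1, 2, 3 and 4. It was 435 with only the 2 groups in the fit, 93 and 48 with the muscle and the erythroid list as covariates, which were themselves called lower, 166 without the 2 skin-poor libraries, 2905 with DESeq2, and 1 (Ddit4, named after its value was seen) without controls 2 and 4. Of the 104 called genes that the naming rule took, 54 stayed called when any 1 mouse was left out, and Eno3, Myl1, Myh2, Myh7, Ldha, Hif1a, Mcm2, Mcm3 and Tcirg1 were among those that did not. Their edgeR adjusted p values ran from 0.0604 to 0.0964 without naive 2, 0.0707 to 0.141 without naive 4, 0.0628 to 0.124 without control 2, 0.0709 to 0.14 without control 3 and 0.0528 to 0.115 without control 4. Some were also lost without naive 1, naive 3 or 1 of the anti-SIRPa mice.

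The second comparison asks what anti-SIRPa changed in arthritic joints. The genes with the largest decreases included chemokines, cytokines and matrix enzymes. Cxcl5 changed by -6.38 ± 0.91 (log2, SE), from 25.9 ± 19.1 to 0.310 ± 0.239 CPM (SD, n = 4 per group; edgeR adjusted p = 0.0158), Mmp3 by -4.89 ± 0.76, from 97.4 ± 74.2 to 3.28 ± 1.30 CPM (edgeR adjusted p = 0.0239), and Il1b by -4.49 ± 0.93, from 8.98 ± 7.45 to 0.393 ± 0.386 CPM (edgeR adjusted p = 0.0338). Csrp3 rose by 2.59 ± 0.44, from 77.6 ± 48.6 to 470 ± 168 CPM (edgeR adjusted p = 0.0237). Each of these calls was lost without anti-SIRPa 1 or anti-SIRPa 2, when edgeR called no gene.

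Other large decreases were those of Adamts4 (-4.05 ± 0.71), Slpi (-4.03 ± 0.84), Timp1 (-3.90 ± 0.64), the lipase inhibitor Angptl4 (-3.26 ± 0.69), Clec4d (-3.19 ± 0.55) and the peptide hormone Apln (-3.01 ± 0.49). By the naming rule, which leaves out antigen receptor segments such as Igkc, the largest increases beside Csrp3 were those of Hectd2os (2.52 ± 0.53), Clec3a (2.12 ± 0.34), Apobec2 (2.03 ± 0.39), the globin Hbb-bs (2.02 ± 0.40), Scg3 (1.98 ± 0.38), Wnt2 (1.98 ± 0.45), the eosinophil attractant Ccl11 (1.94 ± 0.43), Fsd1l (1.92 ± 0.38) and Igsf1 (1.84 ± 0.40). Globin reads can be shared between near-identical genes.

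Of 20 inflammatory cytokines and chemokines, 6 fell and 0 rose. There were 11 and 0 adjusted over the list alone, with a median of -1.49 (camera adjusted p = 1.96e-05, adjusted p = 0.492 with an estimated correlation). Cxcl1 changed by -2.87 ± 0.64 and Ccl7 by -2.83 ± 0.57. Of 20 matrix-degrading enzymes and inhibitors, 8 fell and 0 rose. There were 13 and 1 adjusted over the list alone, with a median of -1.20 (camera adjusted p = 2.84e-06, adjusted p = 0.492 with an estimated correlation). The matrix and tissue repair list had 8 of 22 lower and 0 higher, with Cthrc1 at -3.03 ± 0.60, Col12a1 at -2.19 ± 0.43 and Col3a1 at -2.18 ± 0.42. There were 14 and 0 adjusted over the list alone, with a median of -1.09 (camera adjusted p = 2.1e-05, adjusted p = 0.501 with an estimated correlation). The osteoclast list had 2 of 13 lower, Tnfsf11 (-3.64 ± 0.77) and the proton pump subunit Atp6v0d2 (-2.56 ± 0.58), and 0 higher. There were 7 and 0 adjusted over the list alone, with a median of -1.07 (camera adjusted p = 0.00157, adjusted p = 0.492 with an estimated correlation). No member of the cell cycle list passed on its own among 24, also when adjusted over the list alone, but its median was -1.55 (camera adjusted p = 4.01e-08, adjusted p = 0.5 with an estimated correlation). Gm26917 took 1.92 ± 0.40% of counts in the anti-SIRPa libraries and the muscle list 11.8 ± 1.39%, and receptor genes stood at 8.56 to 12.4 CPM. Without anti-SIRPa 4 the cytokine median was -2.36 and the cell cycle median -2.40, and without control 1 the osteoclast median was -1.95.

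Among myeloid lists, the monocyte and macrophage list had 1 of 21 members higher, Lyve1 (1.51 ± 0.28), which marks resident macrophages and lymphatic endothelium, and 0 lower, 1 and 4 adjusted over the list alone. Its median was -0.56 (camera adjusted p = 0.00678, 0.0583 without control 3, adjusted p = 0.614 with an estimated correlation). The Fc receptor and complement list had 1 of 22 lower, Cfb (-1.96 ± 0.40), and 0 higher. There were 5 and 1 adjusted over the list alone, with a median of -0.55 (camera adjusted p = 0.00491, 0.0652 without control 3, adjusted p = 0.614 with an estimated correlation). The mature neutrophil list had 1 of 10 lower, Clec4d, 3 adjusted over the list alone (median -1.30, camera adjusted p = 0.0429, and 0.112, 0.129 and 0.0575 without control 2, 3 and 4, adjusted p = 0.501 with an estimated correlation). The interferon response list had 1 of 20 lower, Zbp1 (-1.78 ± 0.45), 5 lower and 1 higher adjusted over the list alone (median -0.68, camera adjusted p = 0.00653, 0.103 without control 2, adjusted p = 0.614 with an estimated correlation). The monocyte and macrophage median was -0.37 without control 2 and -0.36 without control 3, and that of Fc receptor and complement genes -0.35 without control 3. The interferon median was -0.38 without control 2, and the neutrophil median -2.47 without anti-SIRPa 4. With the skeletal muscle list as a covariate, which was itself called higher with anti-SIRPa, camera turned the direction of the monocyte and macrophage list (median -0.064, camera adjusted p = 0.859) and of the Fc receptor and complement list (median -0.054, camera adjusted p = 0.942).

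In the other direction, 5 of 78 respiratory chain genes rose and 0 fell. There were 40 and 1 adjusted over the list alone, with a median of 0.47 (camera adjusted p = 9.07e-18, adjusted p = 0.476 with an estimated correlation). Uqcr10 rose by 1.10 ± 0.24, Cox7a1 by 1.16 ± 0.28 and Cox7a2 by 0.94 ± 0.20. The adipocyte list had 6 of 18 higher and 0 lower. There were 10 and 0 adjusted over the list alone, with a median of 0.91 (camera adjusted p = 3.95e-08, adjusted p = 0.322 with an estimated correlation). Adipoq, a fat cell hormone, rose by 1.46 ± 0.32, the lipid droplet protein Plin1 by 1.43 ± 0.30 and the fatty acid carrier Cd36 by 0.94 ± 0.19. The plasma cell list had 4 of 8 higher and 0 lower: the immunoglobulin segments Igkc (6.10 ± 0.84), Igha (3.10 ± 0.69) and Ighm (1.65 ± 0.41), whose reads can be shared between segments, and the transcription factor Irf4 (0.90 ± 0.19). There were 5 and 0 adjusted over the list alone, with a median of 1.27 (camera adjusted p = 0.00171, adjusted p = 0.322 with an estimated correlation). Igkc was at 0.595 ± 0.292 CPM in naive, 0.0827 ± 0.165 in control-antibody and 6.47 ± 3.75 in anti-SIRPa joints. The erythroid list had 2 of 9 higher, Hbb-bs and the transferrin receptor Tfrc (1.53 ± 0.25), and 0 lower. There were 4 and 0 adjusted over the list alone, with a median of 1.16 (camera adjusted p = 0.000313, adjusted p = 0.322 with an estimated correlation). The mast cell list had 1 of 7 higher, Kit (1.30 ± 0.28), and 0 lower. There were 5 and 0 adjusted over the list alone, with a median of 1.06 (camera adjusted p = 0.000179, adjusted p = 0.322 with an estimated correlation). The Schwann cell and nerve list had 3 of 14 higher, Gldn (1.10 ± 0.22), Pou3f1 (1.10 ± 0.23) and Sox10 (0.70 ± 0.18), and 0 lower (median 0.34, camera adjusted p = 0.000188, adjusted p = 0.476 with an estimated correlation). The skeletal muscle list had no member past the threshold (median 0.52, camera adjusted p = 1.61e-05, adjusted p = 0.614 with an estimated correlation), nor had glycolysis and hypoxia (median 0.21, camera adjusted p = 0.0442, 0.0751 without control 4, adjusted p = 0.322 with an estimated correlation). Beside these lists, summed B cell precursor transcripts were at 2.17, 3.28, 9.53 and 0.623 CPM in anti-SIRPa 1, 2, 3 and 4, and at 0.91 to 1.66 CPM in the control-antibody libraries. Medians moved by over 1.5 times for skeletal muscle (0.84 without control 1 and 0.34 without control 2), Schwann cell (0.51 without control 1), glycolysis (0.34 without control 1) and erythroid genes (0.65 without anti-SIRPa 3).

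**Figure D2:**
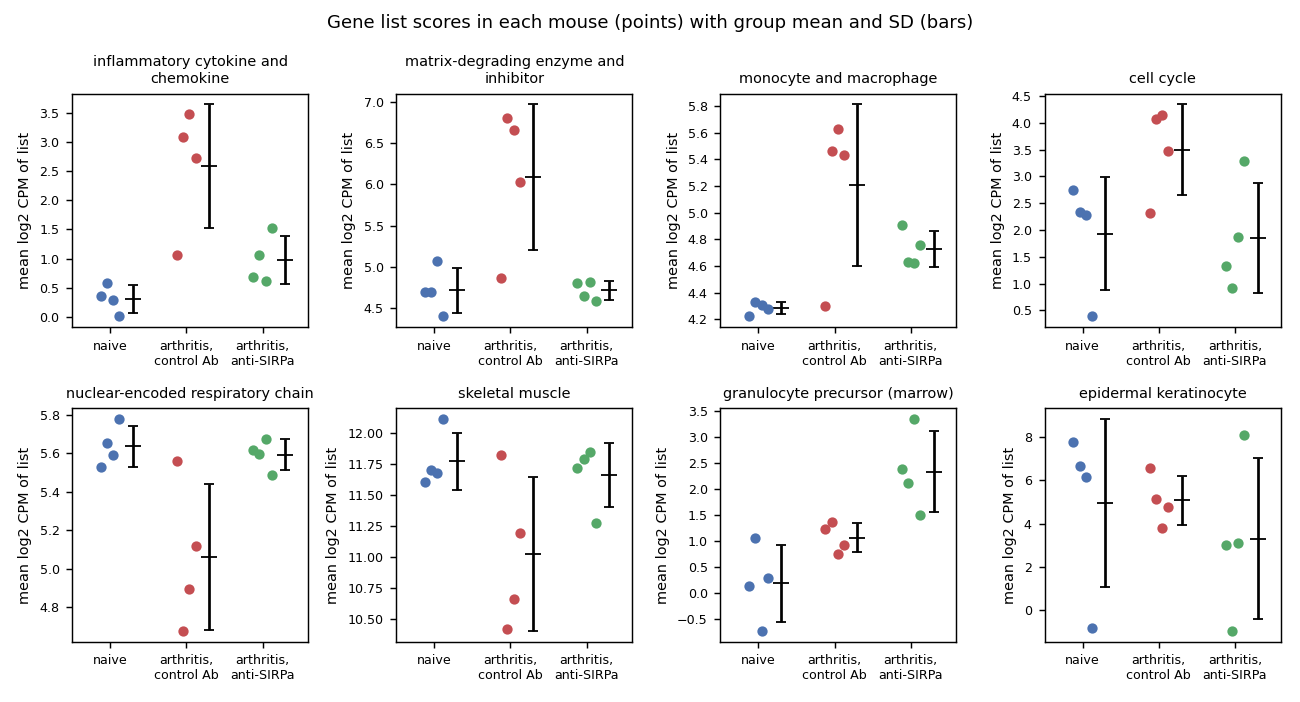
Mean log2 CPM of 8 gene lists in each mouse, by group; each point is 1 mouse and the bar beside the points is the group mean with its SD. Control 1 lies apart from the other 3 control-antibody mice for the cytokine, matrix-degrading, macrophage and respiratory chain lists, and the epidermal list has a larger SD in the naive and anti-SIRPa groups than any difference of its group means.

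In all, edgeR called 548 of 16674 genes, 265 higher and 283 lower, 299 of them at least 2-fold (112 higher and 187 lower). With limma-voom 221 were higher and 124 lower. Among the called genes, 431 had groups that did not overlap, and among all tested genes 10% did, against 2.86% by chance. The count was 0 without anti-SIRPa 1 or 2 (3277 and 3150 genes at an unadjusted p under 0.05), and 1 without control 3 (Plin1) or control 4 (Ddit4). It was 48 without control 2, 3976 without control 1, 173, 173 and 232 without naive 1, 2 and 3, and 144 without anti-SIRPa 3. Fits gave 0 with only the 2 groups in the fit (3284 at an unadjusted p under 0.05), 7 and 0 with the muscle and the erythroid list as covariates (1044 at an unadjusted p under 0.05 for the latter), 0 without the 2 skin-poor libraries or without controls 2 and 4 (3127 and 2247), 345 with limma-voom and 1871 with DESeq2. The erythroid scores of the anti-SIRPa and control-antibody mice did not overlap, so that this covariate also removes the group difference. With it, camera turned the direction of the cytokine (median 0.12), monocyte and macrophage (0.21), Fc receptor and complement (0.17), matrix and tissue repair (-0.085), cell cycle (0.30), skeletal muscle (-0.34), Schwann cell (-0.19) and respiratory chain lists (-0.02). Ddit4 was named after its value was seen.

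The third comparison asks what still differed between anti-SIRPa joints and naive joints. Granulocyte precursor genes stood higher as a list: adjusted over all genes no member passed, but 6 of 8 were higher and 0 lower adjusted over the list alone, with a median of 2.93 (camera adjusted p = 4.61e-09, adjusted p = 0.0359 with an estimated correlation). Mpo, the peroxidase of granule formation, was at 8.23 ± 7.68 CPM against 0.406 ± 0.541 (4.32 ± 1.09, SE; SD, n = 4 per group; edgeR adjusted p = 1.00) and the granule protein Ngp at 9.04 ± 8.09 against 0.995 ± 0.788 CPM. In these mice B cell precursor transcripts, another marker of marrow, were at 2.17, 3.28, 9.53 and 0.623 CPM, against 0.487, 1.4, 0.141 and 1.30 CPM in the naive mice. The immediate early list had 9 of 16 higher and 0 lower adjusted over the list alone and none over all genes (median 0.58, camera adjusted p = 4.61e-09, adjusted p = 0.186 with an estimated correlation). Zfp36 was at 30.3 ± 5.90 CPM against 13.8 ± 3.46 in naive joints, a difference of 1.14 ± 0.18 that did not pass (edgeR adjusted p = 0.476).

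Lists that camera placed higher with no member past the threshold over all genes were monocyte and macrophage (median 0.42, camera adjusted p = 1.28e-07, adjusted p = 0.347 with an estimated correlation), and dendritic cell (0.95, 1.45e-06, adjusted p = 0.256 with an estimated correlation). The cytokine and chemokine (0.80, 4.93e-05, adjusted p = 0.419 with an estimated correlation), interferon response (0.59, 1.41e-05, adjusted p = 0.359 with an estimated correlation), Fc receptor and complement (0.33, 0.000108, adjusted p = 0.533 with an estimated correlation), SIRP family and phosphatases (0.55, 8.47e-06, adjusted p = 0.295 with an estimated correlation) and adipocyte lists (0.65, 3.59e-08, adjusted p = 0.277 with an estimated correlation) did so too. The same held for T and NK cell (0.83, 0.000382, adjusted p = 0.0715 with an estimated correlation), plasma cell (0.63, 0.000681, adjusted p = 0.135 with an estimated correlation), mature neutrophil (1.00, 0.000681, adjusted p = 0.287 with an estimated correlation), B cell and precursor (0.94, 0.00104, adjusted p = 0.298 with an estimated correlation), mast cell (0.41, 0.00442, adjusted p = 0.298 with an estimated correlation) and osteoblast and osteocyte (0.44, 7.02e-05, adjusted p = 0.298 with an estimated correlation). Epidermal (median -0.44, camera adjusted p = 0.00105, adjusted p = 0.739 with an estimated correlation) and hair and nail keratins (median -1.41, camera adjusted p = 0.0036, adjusted p = 0.739 with an estimated correlation) were placed lower. Without naive 1 the epidermal median was 0.23 and without anti-SIRPa 2 it was -0.09, with camera adjusted p values of 0.172 and 0.479, and the hair and nail call was lost without naive 1, naive 2 or anti-SIRPa 2 (camera adjusted p = 0.172, 0.106 and 0.474). The epidermal median was also -0.81 without naive 4, and -0.13, -0.10 and -4.27 without anti-SIRPa 1, 3 and 4. The neutrophil median was 2.13 without naive 2 and 0.66 without anti-SIRPa 3, the dendritic cell median 0.56 without anti-SIRPa 1, the B cell median 1.49 without naive 2 and the mast cell median 0.19 without anti-SIRPa 3. The plasma cell median was 1.43, 1.66, 1.08 and 1.27 without naive 1, 2, 3 and 4, and 1.34 without any 1 of the controls.

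With edgeR, 0 of 16674 genes passed, 675 had an unadjusted p under 0.05 and the smallest adjusted p was 0.476. Limma-voom called 0, DESeq2 20 and edgeR without a filter 4, which were Kit, Slc13a5, Zfp36 and Gm23442, the last named after its value was seen. Groups did not overlap for 4.89% of tested genes, against 2.86% by chance. The genes with the smallest p were Zfp36, the citrate transporter Slc13a5 (2.05 ± 0.40), Kit (1.41 ± 0.28), Fos (2.63 ± 0.48) and Egr1 (1.43 ± 0.28) with positive differences, and Itgb8 (-0.58 ± 0.12), Mast4 (-0.46 ± 0.10), Efna1 (-0.71 ± 0.18), Tmem44 (-1.07 ± 0.28) and Tnfrsf12a (-1.24 ± 0.32) with negative ones.

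Genes called in arthritis lay closer to naive levels with anti-SIRPa. The median treatment fold change was -0.83 for the 979 genes called higher in arthritis and 0.61 for the 742 called lower; 247 of the former were called lower with anti-SIRPa and 217 of the latter higher. Since both comparisons share the control-antibody libraries, unchanged groups were simulated against them. These gave an overlap of 0 and 0.05 on average, but they called only 0.05 genes per direction in arthritis, so that this value is fixed by the lack of calls and says nothing about the overlap. Independent lists of these sizes would share 16.6 and 11.8. The simulated genes varied independently of each other, without differences between libraries in tissue content. Across genes, which are not independent replicates, the covariance of the fold changes was -0.353, against -0.0961 in simulated unchanged groups (-0.106 to -0.0847), a difference of -0.257. With the control libraries split so that no library was shared, it was -0.25 on average (-0.285 to -0.195), but only 3 and 2.33 genes on average were called in opposite directions (0 to 8 and 0 to 10). The medians of these splits were -0.78 and 0.95 on average. In the 3 splits with only 1 to 10 genes called per direction in arthritis they were -1.34 to -0.92 and 0.75 to 2.27. In the 3 splits with 587 to 2368 called per direction they were -0.55 to -0.25 and 0.21 to 0.47. The overlap of 247 and 217 genes was 0 and 0 without control 3, anti-SIRPa 1 or anti-SIRPa 2, 1 and 0 without control 4, and 14 and 27 without control 2. It was also 0 and 0 without the 2 skin-poor libraries or without controls 2 and 4. It was 65 and 73, 52 and 73, 96 and 88, and 93 and 154 without naive 1, 2, 3 and 4. Without anti-SIRPa 3 and 4 it was 51 and 83, and 154 and 199. Without control 1 it was 1736 and 1613, and the covariance was -0.668.

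**Figure D3:**
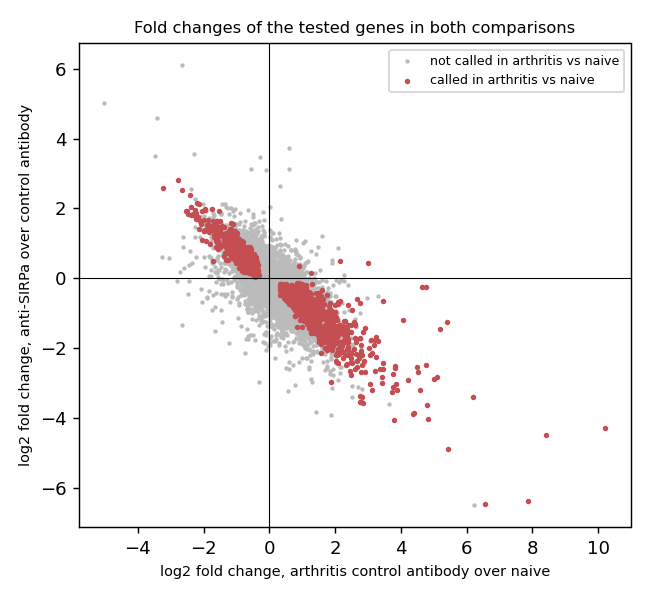
Log2 fold change of each tested gene with anti-SIRPa over control antibody (vertical axis) against its log2 fold change in control-antibody arthritis over naive (horizontal axis); red points are the 1721 genes called in arthritis. Most red points lie in the upper left and lower right, and shared control libraries give part of this slope with no effect.

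The target of the antibody, Sirpa (ENSMUSG00000037902, chromosome 2, 129592835 to 129632228 on GRCm38), rose in arthritis by 0.80 ± 0.23, from 73.4 ± 10 to 128 ± 47.9 CPM (SD, n = 4 per group; edgeR adjusted p = 0.0448), a call lost without any 1 of the naive mice (edgeR adjusted p from 0.0601 to 0.126), any 1 of the anti-SIRPa mice (0.055 to 0.0628) and control 2, 3 or 4 (0.0853 to 0.138). With anti-SIRPa it stood at 90.3 ± 4.01 CPM, a change of -0.51 ± 0.23 that did not pass (edgeR adjusted p = 0.2). The phosphatase gene Ptpn6, which acts downstream of SIRPa, rose in arthritis by 0.93 ± 0.20 (edgeR adjusted p = 0.0154), a call lost without naive 2 (edgeR adjusted p = 0.0501), and did not pass with treatment (-0.56 ± 0.20). Cd47, the ligand, at 0.26 ± 0.14 and -0.21 ± 0.14, and Ptpn11, at -0.33 ± 0.11 and 0.12 ± 0.11, passed in neither. An antibody does not delete its target, so these values do not check the labels.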

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

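The rule for values far from their group was fixed before the data were examined, and no test in this part was chosen after its result was seen. Of 432 groups of 4 mice, 25 had 1 mouse whose gap to the nearest of the others divided by the group's range exceeded the critical value of Dixon's test, where chance flags about 1 in 20 groups, or 21.6 of these. The number is close to that.

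In control 1 the far values, with gap over range and log2 CPM or list score, were Igkc (1.00 and -1.08), Oasl2 (0.941 and 2.04), Xist (0.896 and 9.04), Ms4a7 (0.874 and 1.14), the Schwann cell score (0.867 and 4.62), the synovial fibroblast score (0.859 and 5.32), the monocyte and macrophage score (0.854 and 4.30) and Cthrc1 (0.83 and 2.12). In control 2 they were the plasma cell score (0.921 and 2.31) and the depth (0.838 and 6893969 counts).

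In anti-SIRPa 4 they were the share of Gm26917 (0.893 and 2.52%) and its log2 CPM (0.842 and 14.4), Hif1a (0.864 and 6.97), Myh7 (0.858 and 11.2) and Mcm3 (0.832 and 4.70), and in anti-SIRPa 3 Uqcr10 (0.862 and 6.05) and Selp (0.847 and 2.98).

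Among naive mice they were Il1b (1.00 and -2.23), Ccl2 (0.883 and 0.629) and Lyve1 (0.846 and 6.33) in naive 2, Efna1 (0.971 and 4.25) in naive 1, Col5a2 (0.966 and 8.76) in naive 3, and Atp6v0d2 (0.969 and 1.54), the hair and nail keratin score (0.877 and -1.91) and the leukotriene score (0.836 and 2.18) in naive 4.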

How the results depend on the processing

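The newer quasi-likelihood fit, the epidermal covariate, the background subtraction and both sets of 2 left-out mice were chosen after seeing the data. For genes called in arthritis and with anti-SIRPa, RLE size factors (1687 and 548), scaling without 4 lists (1712 and 548), a stricter filter (1790 and 631), no filter (1487 and 646), a fit without robust moderation (1634 and 524), the newer fit (1871 and 701), the epidermal covariate (2181 and 755) and background subtraction (1721 and 558) stayed within 1.5 times of 1721 and 548, as did limma-voom in arthritis (1163). Counts in arthritis were 435 with only the 2 groups compared, 93 with the muscle covariate, 48 with the erythroid covariate, 166 without naive 4 and anti-SIRPa 2 (the 2 skin-poor libraries), 1 without controls 2 and 4 (the 2 background-rich libraries), 2905 with DESeq2 and 800 with a 2-fold minimum. With anti-SIRPa they were 0, 7, 0, 0, 0, 1871 and 299 under the same settings, and 345 with limma-voom. The edgeR counts of 0 had 3284 (only 2 groups), 1044 (erythroid), 3127 (skin-poor) and 2247 (background-rich) genes at an unadjusted p under 0.05. The muscle and erythroid lists were themselves called between these groups, so that these covariates also remove part of the group difference. Leaving out mice lowers the number of samples, and a 2-fold minimum only removes genes. For the other settings the cause was not tested. For anti-SIRPa against naive, the count of 0 became 4 with no filter and 20 with DESeq2.

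Without 1 mouse, counts in arthritis ran from 412 (control 3) to 4694 (control 1), and with anti-SIRPa from 0 (anti-SIRPa 1 or 2; 3277 and 3150 unadjusted) to 3976 (control 1). Against naive they ran from 0 to 0. The covariance of both sets of fold changes ran from -0.67 to -0.30, the median change with anti-SIRPa of genes called higher in arthritis from -1.10 to -0.82, and of those called lower from 0.63 to 0.86. These medians moved by more than the spread to -1.12 and 0.97 without the skin-poor libraries, to -1.32 without the background-rich libraries, which is the value of the 1 gene then called higher, and to 0.95 (called lower) as a mean over the splits of the controls, some of which called 1 to 10 genes. The cause was not tested. The target check called 2 genes, and 1 with no filter, 1 with the replicate block, 1 with limma-voom and 0 with only the 2 groups compared, either covariate of muscle or erythroid genes, either set of 2 left-out libraries or a 2-fold minimum (0 to 6 without 1 mouse). Of the camera tests 55 passed, 1 with an estimated correlation and 22 with fry (54 to 62 without 1 mouse). The cause was not tested.

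With the replicate number as a block, 735 genes were called in arthritis, 78 with anti-SIRPa and 0 against naive (503 at an unadjusted p under 0.05, edgeR). With this block, 28 genes called higher in arthritis were called lower with anti-SIRPa and 40 the other way, in place of 247 and 217. The numbers do not pair the mice: correlations of same-numbered deviations were 0.207, 0.015, -0.016 and -0.003 in arthritis, -0.127, -0.012, 0.099 and -0.083 with anti-SIRPa and -0.339, -0.546, -0.075 and -0.80 against naive, and not every mouse correlated best with its own number.

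The camera direction turned in 24 list tests that passed the threshold in the main fit or under the setting. Turns of tests that passed in neither were not counted. The 24 are given here with the list median, which itself changed sign in 18 and kept it in 6 (histone with anti-SIRPa, macrophage and Fc receptor with the muscle covariate, and matrix repair). In arthritis the direction turned for skeletal muscle with the muscle covariate (0.089). With anti-SIRPa it turned for histone without a filter (0.087), and with the muscle covariate monocyte and macrophage (-0.064), Fc receptor and complement (-0.054), skeletal muscle (-0.028) and histone (0.506). With the erythroid covariate it turned for monocyte and macrophage (0.208), inflammatory cytokine (0.120), Fc receptor (0.173), matrix repair (-0.085), tendon (0.509), skeletal muscle (-0.341), erythroid (-0.306), Schwann cell (-0.192), cell cycle (0.303), immediate early (0.443), mitochondrial-encoded (-0.330), respiratory chain (-0.022) and histone (1.108). Against naive it turned for matrix-degrading enzyme (0.353) and cell cycle (0.688) with the erythroid covariate, and epidermal (0.018), cell cycle (0.291) and histone (0.163) with the epidermal covariate. In 4 of the 24 the covariate was the list's own mean (skeletal muscle in both comparisons, erythroid and epidermal), which removes the change by construction. For the others the cause was not tested. Other list tests kept their side of the threshold in 955 of the tests in arthritis, 917 with anti-SIRPa and 930 against naive, with 62, 59 and 42 weaker and 15, 40 and 57 stronger. Of the named genes, 104 were called in arthritis, and 54 of them stayed called whichever 1 mouse was left out. With anti-SIRPa 68 were called, and 0 of them stayed called in this way. No named gene changed sign where it was called in the main fit or under the setting. Where it was called in neither, the sign changed by at least the SE in 14 values in arthritis. There were 43 such values with anti-SIRPa, 21 of them with the erythroid covariate, and 9 against naive. The depth of 6893969 counts in control 2 limits low genes there.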

Other observations

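Among the tests reported here, the test of arthritis by halving the naive mice was reworded after counts of genes per setting were seen, its mean over only those halvings that called genes was set after its result was seen, and the test of serum or antibody for granulocyte precursor genes and the epidermal covariate were chosen after the data were seen.

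Vessel markers split in arthritis. The adhesion molecule Selp rose by 3.35 ± 0.54 (log2, SE, n = 4 per group), Lyve1 changed by -1.44 ± 0.28 and the tight junction gene Cldn5 by -0.92 ± 0.17. Of 19 endothelial genes 3 rose and 3 fell, 5 and 4 adjusted over the list alone, with a median of 0.18 where camera gave Down (camera adjusted p = 0.991), and with anti-SIRPa 3 rose and 2 fell (median -0.27, camera adjusted p = 0.751). Synovial fibroblast genes also went both ways, 6 of 19 up and 5 down in arthritis, 7 and 6 adjusted over the list alone, with a median of 0.23 where camera gave Down (camera adjusted p = 0.991): Pdpn, a marker of lining cells, rose by 1.97 ± 0.32 and Tspan15 changed by -0.95 ± 0.13. With anti-SIRPa 4 rose and 5 fell, 6 and 6 adjusted over the list alone, with a median of 0.04 and a mean of -0.48 (camera Up, adjusted p = 0.687). Among chondrocyte genes 1 of 14 rose and 3 fell in arthritis (median -0.02, camera adjusted p = 0.569), with Col10a1 at -1.49 ± 0.27, and 2 rose with anti-SIRPa (median 0.27, camera adjusted p = 0.172). In arthritis the calls of Acan, which rose, and Col9a1, which fell, were lost without any 1 naive mouse, control 2, 3 or 4, or anti-SIRPa 1, 2 or 3. That of Chad was lost without control 3 (edgeR adjusted p = 0.0631). Alternatively activated macrophage genes had 3 of 18 higher and 2 lower in arthritis (median 0.00, camera adjusted p = 0.903), with Trem2 at 1.27 ± 0.27. The call of Il4ra was lost without any 1 mouse except control 1, that of Gas6 without naive 2, 3 or 4 or control 2 or 3, and that of Axl without control 3. In the comparison of anti-SIRPa with the control antibody 1 was higher and 1 lower (median 0.31, camera adjusted p = 0.497). Without anti-SIRPa 1 or anti-SIRPa 2, edgeR called 0 genes in this comparison (3277 and 3150 at an unadjusted p under 0.05).

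Further lists in arthritis were adipocyte (1 of 18 lower, Cd36, with an edgeR adjusted p of 0.0509 and 0.0513 without naive 2 and 3 and 0.0637 and 0.0568 without control 3 and 4; median -0.31, and -0.20 and -0.17 without naive 1 and control 2, camera adjusted p = 0.0117, 0.204 without control 2, adjusted p = 0.516 with an estimated correlation) and erythroid (1 of 9 lower, Tfrc; median -0.27, and -0.80, -0.46 and -0.14 without control 1, 2 and 4). The camera adjusted p of the erythroid list was 0.0227, and 0.0602, 0.109, 0.0508 and 0.146 without naive 1, 2, 3 and 4, 0.0594 and 0.0876 without control 1 and 3, and 0.0725 and 0.0611 without anti-SIRPa 1 and 2 (adjusted p = 0.455 with an estimated correlation). No mast cell gene of 7 passed (median -0.56, and -0.35 without naive 4, camera adjusted p = 0.0301, 0.0508 without naive 3 and 0.197 without control 1, adjusted p = 0.455 with an estimated correlation). The list of RNA types, a library check, holds structural, ribosomal and long noncoding RNAs and the protein-coding Lars2. It had 3 of 12 members higher in arthritis (median 0.32, camera adjusted p = 0.0105, 0.062 without naive 1, adjusted p = 0.455 with an estimated correlation) and 4 lower with anti-SIRPa (median -0.50, camera adjusted p = 0.00222, adjusted p = 0.476 with an estimated correlation), Gm26917 among them. The arthritis call of Lars2 was lost without naive 1, 2 or 4 or control 2 or 4, and that of Gm42418 without naive 4 or control 3. With camera adjusted p values above the threshold in arthritis were granulocyte precursor (median 0.29 and camera adjusted p 0.21, with 2 of 8 members called higher), leukotriene and eicosanoid (0.21 and 0.991), osteoblast and osteocyte (0.24 and 0.252), tendon (0.40 and 0.252), B cell and precursor (1.49 and 0.21), plasma cell (-0.16 and 0.252), T and NK cell (0.46 and 0.406), megakaryocyte and platelet (0.23 and 0.394), mitochondrial-encoded (-0.29 and 0.1), ribosomal protein (0.04 and 0.952), histone (0.07 and 0.952, with camera giving Down), epidermal (-1.09 and 0.903) and hair and nail keratin genes (-1.16 and 0.252). With anti-SIRPa the epidermal list had a median of 0.61 where camera gave Down (camera adjusted p = 0.107). Single members called with edgeR in these lists were 1 higher and 1 lower among leukotriene genes, 2 higher among tendon genes, 1 lower among plasma cell genes, 1 higher each among osteoblast, B cell, T and NK cell and platelet genes, and 3 higher among ribosomal protein genes. Of these members, only the plasma cell and the platelet gene stayed called without naive 2 or without control 3. The 3 ribosomal calls were also lost without naive 3 or 4 or control 2 or 4, and 0 ribosomal genes passed adjusted over the list alone. The sex-linked list had Xist as its 1 measured member, at 0.32 ± 0.14 in arthritis (edgeR adjusted p = 0.148).

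Genes called higher in control-antibody arthritis came from a group in which controls 2 and 4 carried reads on receptor genes of nose and tongue, at 545 and 215 CPM. If reads spread along the genome had made the increases, a background in proportion to gene length should account for at least 50% of the rise of most of the 979 genes; it did so for 0% of the 978 with an exonic length, with a median share of 1.26%, which argues against this explanation. Genes called with controls 2 and 4 against 2 naive mice had a median fold change of 0.911 in controls 1 and 3 against the other naive mice (SD 0.401 over the 3 of 6 halvings that called any gene), but the halving with 125 called genes gave 0.472, and those with only 6 and 14 gave 1.257 and 1.005. Arthritis thus stays open as an explanation, as a hypothesis. Only 1 of the 35 splits of the 8 mice, the real one, gave as many as 1721 genes, which is the smallest share these splits can give. The highest other split gave 1639 with naive 3 and control 1 exchanged. The real count itself ran from 412 without control 3 to 4694 without control 1. With 1 of 35 as the smallest possible share and another split at 1639, the splits do not exclude chance for the real count.

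The cell cycle list was lower with anti-SIRPa, with a median of -1.55 (jackknife SE 0.961; -2.40 without anti-SIRPa 4; adjusted p = 0.5 with an estimated correlation). If unequal amounts of skin in the dissected pieces were the cause, the median should approach 0 with the epidermal list as a covariate; it was -1.555 (jackknife SE 0.525; -1.842 to -1.157 without 1 mouse), with 5 members called in place of 0, which argues against skin as the whole cause. With that covariate camera at its preset correlation still placed the list lower (camera adjusted p = 3.15e-08), so that an effect of the antibody stays open, as a hypothesis. The medians were -0.32 and 0.30 with the muscle and erythroid covariates (camera adjusted p = 0.0231 and 0.792). Both lists were themselves placed higher with anti-SIRPa by camera. The erythroid scores of the 2 groups did not overlap, so that the erythroid covariate also removes the group difference and decides nothing here. The muscle scores overlapped (exact permutation p = 0.143) and no muscle gene was called. But the overlap came from control 1 alone, at 11.817. Controls 2, 3 and 4 stood at 10.419, 10.659 and 11.191, below the anti-SIRPa scores of 11.275 to 11.841. The muscle covariate thus also removes part of the group difference and does not decide between the antibody and unequal amounts of muscle in the pieces. Both stay open. For the treatment comparison chance cannot be excluded: 2 of the 35 splits, the real one included, gave at least 548 genes (0 without anti-SIRPa 1 or 2 and 3976 without control 1), and the highest other gave 2333 with control 1 exchanged for anti-SIRPa 4. A split that calls several times the real count points to a structure of the samples, in which control 1 resembles treated and naive mice.

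Granulocyte precursor genes were higher with anti-SIRPa than in naive joints. More bone marrow in the dissected pieces may be a cause. Summed B cell precursor transcripts, a marker of marrow, were higher by a log2 ratio of 2.217 ± 0.745 (interval 0.757 to 3.677) against naive. They were highest in anti-SIRPa 3 at 9.53 CPM and stood at 0.623 CPM in anti-SIRPa 4. Against the control antibody they were higher by 1.514 ± 0.726 (0.091 to 2.936). Summed hemoglobin transcripts were higher by 1.716 ± 0.419 (0.895 to 2.536) against the control antibody. Against naive, hemoglobin was higher by 0.876 ± 0.405 (0.082 to 1.671). These intervals assume a normal distribution, which makes them too narrow for 4 mice per group. Tested without adjustment, the B cell precursor difference against the control antibody and the hemoglobin difference against naive did not pass the threshold. The other differences passed. The granulocyte precursor score was also higher with anti-SIRPa than with the control antibody, with each of 4 mice above each of 4 controls. The exact permutation p was 0.0286, the smallest that can be had, and 0.132 adjusted over lists. But 0 members were called with edgeR (3 adjusted over the list alone). The list test did not pass either (camera adjusted p = 0.0601, and 0.492 with an estimated correlation), so that an effect of the antibody stays open beside marrow. In the same comparison the B cell and precursor list as a whole did not pass (median -0.14, camera adjusted p = 0.659), so that marrow is left open too. For serum alone, control-antibody arthritis against naive, the scores overlapped (exact permutation p = 0.0857; camera adjusted p = 0.21), but 2 of 8 members were called higher with edgeR, so that an effect of serum on single genes stays open too. These were Lcn2 (4.07 ± 0.66, edgeR adjusted p = 0.00753) and Chil3, with 51 counts against 2, a ratio of 31.6 with a counting interval of 8.3 to 268 (edgeR adjusted p = 0.0203, and 0.0569, 0.0501, 0.0641 and 0.0668 without naive 1, 2 and 4 and control 3).

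For the anti-SIRPa against naive count of 0 genes (675 at an unadjusted p under 0.05 with edgeR, 20 called with DESeq2, 0 with limma-voom), all 35 of 35 splits give at least as many by construction, so that the splits say nothing about chance. The highest other gave 873 with naive 4 and anti-SIRPa 4 exchanged, which points to a structure of the samples apart from their groups.

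Per mouse, 25 of 111 list comparisons had an exact two-sided permutation p under 0.05, where 0.0286 is the smallest that 4 against 4 mice can give, and none passed after adjustment over lists. The smallest adjusted values were 0.176 in arthritis, 0.132 with anti-SIRPa and 0.0961 for anti-SIRPa against naive.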
